A study of Caenorhabditis elegans with 2 samples.

How the data were processed

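The measurements were ChIP-seq peak lists from embryos of mixed stages of the Caenorhabditis elegans strain OP727, which carries an integrated transgene for CEH-83 fused to GFP and FLAG tags together with a rescuing unc-119 gene. Per the sample description, the immunoprecipitation used an antibody against GFP, while the antibody label itself reads ceh-83. Per the labels, the embryos were obtained by egg bleaching and given an age of 1 hour. Chromatin was sheared by sonication to 200 to 800 bp, also per the labels. Per the labels, there were 2 biological replicates from separate biological samples, and both formed 1 group. A control library is named in the labels and in the deposited file listing but was not analysed here.

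The deposited files were lists of regions on assembly ce11 in the 10-column narrowPeak format. Per the deposited file listing, 1 relaxed list was made for each replicate alignment against a control alignment, 1 for both alignments pooled, and the IDR list was derived from these. The IDR threshold, the aligner, the peak caller and their versions are not given in the sources used here. The deposited signal value of each region is the authors' measure of the region against the control, and its scale differs between lists. The deposited score in the q-value column was below 0 in 95.3% of pooled regions, so it was not read as a -log10 q-value and enters no result. The p-value column is -1 throughout and the column for a scaled IDR is 0, so neither was used. Summit positions were taken from the authors' summit column. Read totals are not given in the sources used here, so depth is unknown and no value was corrected for it.

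The coordinates were checked against the reference sequence of the same assembly (WBcel235), and all regions lay within its chromosomes. Genes and transcripts came from Ensembl release 115. Because that annotation gives some paralogues 1 shared name, symbols were taken from the RefSeq annotation of the same assembly by WormBase identifier, which matched 19965 of 19973 protein-coding genes and all 612 tRNA genes. A gene belonged to a list if its symbol in either annotation met the list's rule. Coordinates in the text count from 1.

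IDR summits were compared with background summits, defined as the 28364 regions of the pooled list with no IDR summit within 500 bp. Promoter windows ran from 1000 bp upstream to 200 bp downstream of a protein-coding gene start, along the strand. Non-coding genes were extended by 200 bp to either side. Proportions were compared by two-sided Fisher's exact tests with sample odds ratios and conditional exact 95% intervals, shares carry 95% Clopper-Pearson intervals, a share of 0 is given with the limit that 3 counts of the total set, and families of tests were adjusted by the Benjamini-Hochberg method at 0.05. The promoter count was also compared with 100000 circular shifts of the peaks along each chromosome, which keep the spacing of peaks. Neighbouring regions and genes are not independent, and these tests treat them as if they were. With 1 group, no test compares samples.

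Gene lists were tested among the 7129 protein-coding genes with a pooled summit in the promoter window, since only these could have been called. Sequences were searched on both strands in windows of 50 bp to either side of the summit. Fixed sequences were compared with windows of the same peaks centred 300 bp away (exact McNemar test) and with 4 background windows per peak matched on G and C content, drawn with a fixed seed. The 2080 words of 6 bases, with reverse complements joined, were compared with the same matched windows. For uniqueness of sequence, all words of 31 bases within 100 bp of a summit were counted in the whole genome. For tRNA genes in unique sequence, the words within 100 bp of the gene midpoint were taken instead, which is a different measure. The word length was chosen here, as the read length is not given in the sources used here. The B box was searched as GWTCRANNC, a pattern written down after the enriched words had been seen. A summit counted as shared with a replicate when a summit of that replicate's 1258 highest regions lay within 100 bp.

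The word and list tests were tested on simulated data. Among 2080 words over 1200 simulated peak windows, the test called 20 of 20 words planted in 5% of windows and 4 of 20 planted in 2%, with no call at 2% among the 1814 words that shared no run of 5 bases with a planted one. At 10% it called 20 of 20 and 10 of 1796 others (0.557%). Among 7000 simulated genes, a list of 60 with a raised odds ratio of 3 was called in 59.5% of 200 runs, and one of 20 in 13.5%. The simulated windows were random bases with the same G and C content for peaks and background, and the simulated genes were independent. Real windows and genes are not, so these rates may not carry over to the real data.

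The genes to be named, the gene lists, the tests and most alternatives were fixed before the data were examined. The text names ceh-83 and unc-119, the 10 protein-coding genes with the highest IDR peak in their promoter window, up to 4 bound members of each list by signal, and the 3 highest IDR peaks outside promoter windows; other features are said to be chosen after their values were seen. Alternatives were other summit distances, windows, backgrounds, transcript starts and list lengths, the 629 IDR peaks of higher signal, and each replicate left out in turn, with the 1258 highest regions of the other replicate in place of the IDR peaks. Results without peaks at tRNA, snoRNA and snRNA genes, and with RefSeq names alone, were added after the data were seen. The analysis ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.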

Results

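CEH-83 is the product of a homeobox gene of the nematode Caenorhabditis elegans. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in embryos of mixed stages, with an antibody against GFP that pulls down a GFP-tagged CEH-83 made from an integrated transgene. There was 1 group of 2 biological replicates, and the labels name no treatment or second genotype. The comparisons open to this design were between the replicates, and between the peaks and other regions of the genome. No library of untagged animals was analysed, so a CEH-83 peak or a bound gene below means an IDR peak only. Whether CEH-83 itself is bound there was not tested. The plan listed genes of RNA polymerase III beforehand as frequent non-specific ChIP sites. Each library came with a relaxed list of 30000 regions, and the pooled reads gave a further list of 30000. The authors drew 1258 peaks from these by the irreproducible discovery rate (IDR), which sets how many ranked regions recur between replicates. Read totals are not given in the sources used here, so the depth of each library is unknown, and the intervals below cover counting error over peaks or genes only.

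The 1258 IDR peaks were the 1258 regions of highest signal in the pooled list. Their signal, the authors' own value per peak and used here only to describe and rank peaks within a list, ran from 190 to 1777 with a median of 228. All but 13 of the peaks were 444 bp wide. The 10 highest peaks were all among those 13. The narrowest of all peaks spanned 117 bp. Together the peaks covered 556 kb.

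The strongest CEH-83 peaks lay at genes of small non-coding RNAs. The highest peak of all, with a signal of 1777, spanned V 12303457 to 12303762 (ce11) in an intron of frm-7, at the snoRNA genes C51F7.3 and C51F7.4. The second, with a signal of 1692, spanned II 11960675 to 11960967 in intergenic sequence at the snoRNA gene W03C9.9. The third, with a signal of 1528, spanned V 11314091 to 11314339 in an intron of cutl-18, at the snoRNA gene T03F7.8. Small nucleolar RNAs (snoRNAs) guide the chemical modification of ribosomal and other RNAs. Among the 10 highest peaks, 6 had their summit within 200 bp of a snoRNA gene, 2 of a microRNA gene, 1 of a tRNA gene and 1 of no small RNA gene. The microRNA genes were mir-51 and mir-52, and the tRNA gene was the leucine tRNA gene C04A11.t1; these 3 were chosen after their values were seen.

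Among the small RNA classes (tRNA, snoRNA, snRNA, microRNA and piRNA), tRNA genes held the most IDR summits. In all, 236 of the 1258 IDR summits (18.8%) lay within 200 bp of a tRNA gene, against 129 of 28364 background summits (0.455%), an odds ratio of 50.5 (95% interval 40.2 to 63.7). The background here was the regions of the pooled list with no IDR summit within 500 bp. Of the 612 annotated tRNA genes, 242 had an IDR summit (39.5%, 95% Clopper-Pearson interval 35.6 to 43.5). The share did not differ detectably between amino acids. The smallest adjusted p over the 21 tRNA types was 0.706, for the histidine tRNA genes with 3 of 20 (Fisher's exact test). Summits stood a median of 23 bp inside the tRNA gene start, with an interquartile range of -7.5 to 56.25 bp. Background summits at tRNA genes had a similar median of 28 bp and a wider range (-37 to 94 bp), so the median position does not set the IDR summits apart.

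At snoRNA genes the IDR summits stood upstream of the gene. There were 68 IDR summits within 200 bp of a snoRNA gene (5.41%, against 0.314% of background summits; odds ratio 18.2, 95% interval 13.0 to 25.3). Their median position was 41 bp upstream of the gene start (-41 bp, interquartile range -61 to -11.5 bp), against 65 bp inside the gene for background summits. Of these summits, 54 of 68 (79.4%) were upstream, against 35 of 89 background summits at snoRNA genes (Fisher's exact p = 4.2e-07, chosen after the positions were seen). In all, 64 of 346 snoRNA genes (18.5%, 14.5 to 23) had an IDR summit. Those inside a protein-coding gene had one in 39 of 216 cases and those outside in 25 of 130.

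**Figure D1:**
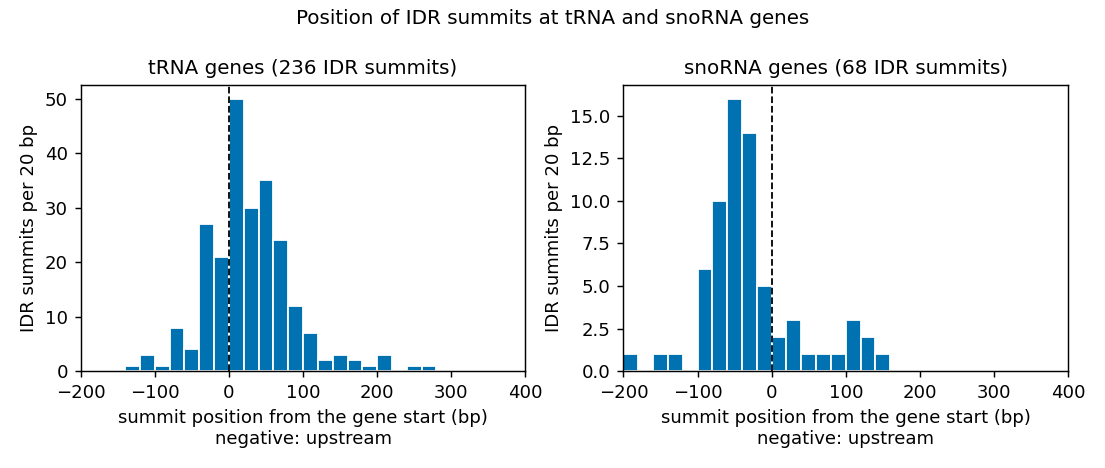
Position of the IDR summits within 200 bp of tRNA genes (left, 236 summits) and snoRNA genes (right, 68 summits). The x axis gives the distance in bp from the nearest gene start along the direction of transcription, the y axis the number of summits per 20 bp. The tRNA summits centre at 23 bp inside the gene and the snoRNA summits at -41 bp, upstream of it.

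Other non-coding classes were also above the background. Small nuclear RNA genes held 18 summits (1.43% against 0.141%; odds ratio 10.3, 95% interval 5.53 to 18.4). Among these, the genes of spliced leader 2, the RNA joined to downstream genes of operons, had a summit in 6 of 18 cases (sls-2.1, sls-2.2, sls-2.4, sls-2.5, sls-2.8 and sls-2.9). The spliced leader 1 genes had one in 0 of 12, which allows a share of up to 25% (3 counts of the total). Whether regions could be called at the spliced leader 1 genes was not tested. The difference between these families did not reach the threshold (Fisher's exact p = 0.0568), and the families were chosen after their values were seen. MicroRNA genes held 15 summits (odds ratio 7.59, 3.92 to 13.9). The broad class of other non-coding RNA genes held 314 (25% against 5.29%; odds ratio 5.96, 5.17 to 6.85), many of them beside tRNA or snoRNA genes. Away from tRNA, snoRNA and snRNA genes, 135 of 937 peaks were still at this class (14.4% against 4.94%; odds ratio 3.24, 2.66 to 3.93).

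The classes that fell below the background were piRNA genes and pseudogenes. The germline's piRNA genes, of which 15363 are annotated, held 10 summits (odds ratio 0.428, 0.204 to 0.797). With no margin around the genes none was hit and that call ended (adjusted p = 0.460, Fisher's exact test). Pseudogenes held 8 (odds ratio 0.250, 0.107 to 0.497). All 7 of these classes passed the threshold of 0.05 after Benjamini-Hochberg adjustment over 8 classes (two-sided Fisher's exact tests), with adjusted p from 8.4e-234 at tRNA genes to 0.00506 at piRNA genes. The 20 ribosomal RNA genes had no summit in the IDR list or in the background. Only 14% of the IDR summits at tRNA genes lay in sequence of which at least 90% was unique in 31-base words, against 98.5% at snoRNA genes, so signal at tRNA genes may be shared among copies. Among summits in such unique sequence the order of these classes turned, with an odds ratio of 24.0 (17 to 33.9) at snoRNA genes and 18.2 (11.3 to 29.0) at tRNA genes, a comparison chosen after the data were seen.

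**Figure D2:**
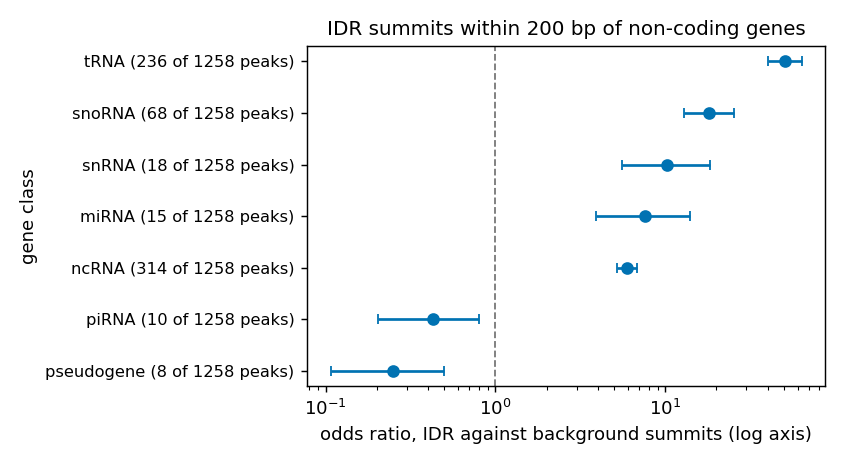
Odds ratio of IDR against background summits within 200 bp of each non-coding gene class, on a log axis, with exact 95% intervals. The tRNA genes, mostly in repeated sequence, stand highest at 50.5 and the pseudogenes lowest at 0.250; the dashed line marks an odds ratio of 1.

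The share of peaks at tRNA, snoRNA and snRNA genes fell with rank. These genes accounted for 40 of the 50 highest peaks (80%, 95% interval 66.3 to 90) and for 69 of the peaks ranked 101 to 200 (69.0%). Among ranks 801 to 1258 the share was 6.11%, and among ranks 10001 to 30000 of the pooled list it was 0.835%. Promoter windows of protein-coding genes showed no such fall within the IDR list, with 30% of the first 50 and 34.9% of ranks 801 to 1258. Over all 1258 peaks, 321 (25.5%, 23.1 to 28.0) lay at these 3 classes of gene.

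**Figure D3:**
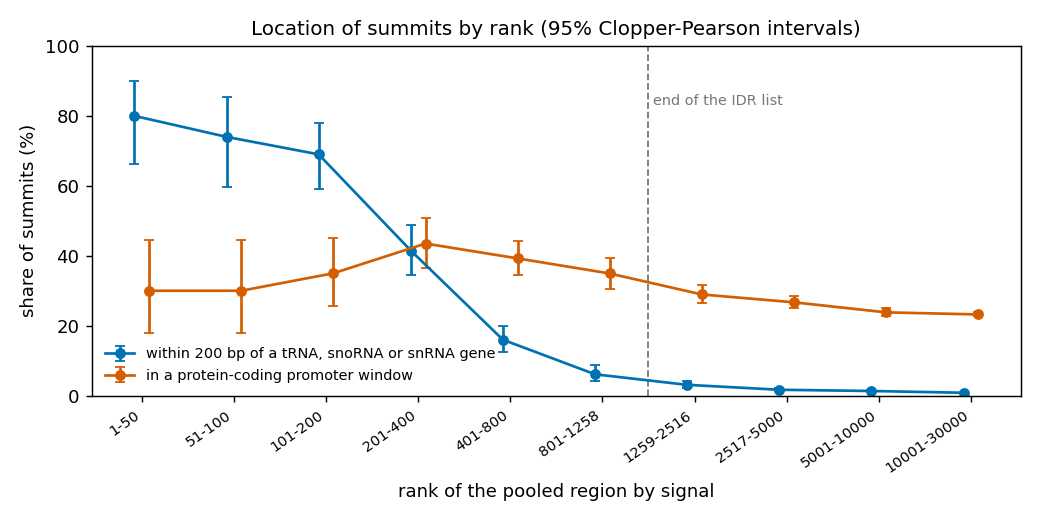
Share of summits (y axis, percent) within 200 bp of a tRNA, snoRNA or snRNA gene (blue) and in a protein-coding promoter window (orange), by rank of the pooled region (x axis), with 95% Clopper-Pearson intervals. The blue share falls from 80% at ranks 1 to 50 to 0.835% at ranks 10001 to 30000.

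CEH-83 peaks were also more frequent in promoters of protein-coding genes than the background regions were. In all, 469 IDR summits (37.3%, 34.6 to 40) lay in a window from 1000 bp upstream to 200 bp downstream of a gene start, against 23.8% of background summits. The odds ratio was 1.91 (95% interval 1.69 to 2.15; two-sided Fisher's exact p = 1.8e-25). It was 2.38 (2.08 to 2.72) once the 321 peaks at tRNA, snoRNA and snRNA genes were set aside, a comparison chosen after the data were seen. When the peaks were shifted together around each chromosome, a mean of 264 ± 15 summits (SD over 100000 shifts) fell in promoters, and the permutation p was 2e-05, the smallest these shifts can give. Coding exons outside promoters held fewer IDR summits than background summits (8.43% against 19.1%; odds ratio 0.390, 0.315 to 0.477). Introns outside promoters also held fewer (28.6% against 32.3%; odds ratio 0.839, 0.739 to 0.952), while 42.4% of the peaks at tRNA, snoRNA and snRNA genes were intronic.

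The promoters with the highest peaks stood mostly beside a small RNA gene. The peak at I 8259442 to 8259653, with a signal of 1490, lay in the promoter of the chemoreceptor gene sre-23 at the snoRNA gene ZK265.10. The promoter of T02E1.2 had a peak of 1282 at a snoRNA gene, that of egg-5, needed for egg activation, one of 916 at sls-2.4, and that of wrt-3, a hedgehog-related gene, one of 805 at a snoRNA gene. C28G1.2 and sec-15, which encodes an exocyst subunit, shared a peak of 865 at a tRNA gene, and the peak of 804 at F28H6.7 was also at a tRNA gene. Only 3 of the 10 genes had a peak with no such neighbour. K12H4.5 had a peak of 1271 at III 8043859 to 8044077. The divergent pair ears-2, a glutamyl-tRNA synthetase gene, and uncp-18 shared a peak of 806 at IV 390297 to 390740. All 10 of these genes had their peak among the 1258 highest regions of both replicates.

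Ribosomal protein genes had bound promoters more often than other genes. Of the 7129 protein-coding genes with a pooled summit in the promoter window, 603 (8.46%) had an IDR summit there, but 21 of 66 ribosomal protein genes did (31.8%; odds ratio 5.20, 95% interval 2.92 to 8.97; adjusted p = 8.4e-07, Fisher's exact test over 17 lists). The highest were rpl-3 with a signal of 745, rpl-15 with 563, rpl-18A with 443 and rps-19 with 427, none of them at a tRNA, snoRNA or snRNA gene. Their summits stood a median of -317 bp from the gene start. Among all bound genes the median was -274 bp.

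Histone and respiratory chain genes were also bound more often. Histone genes had an IDR summit in 8 of 30 cases (26.7%; odds ratio 3.97, 1.52 to 9.32; adjusted p = 0.0233, Fisher's exact test). They included his-59 and his-60, which share 1 peak of 375, and his-31 and his-67 with peaks of 319 and 318. Mitochondrial respiration genes had one in 7 of 28 cases (25%; odds ratio 3.64, 1.3 to 8.93; adjusted p = 0.0312, Fisher's exact test). The cytochrome c oxidase genes cox-5B and cox-5A had peaks of 414 and 315, cox-6A a lower one at an snRNA gene, and cyc-1, for cytochrome c1, one of 291. These calls for histone and respiration genes ended with the narrower window of 500 bp upstream to 100 bp downstream (odds ratios 3.00 with 21 genes tested and 3.04 with 25; adjusted p = 0.181 for each, Fisher's exact test), while that for ribosomal protein genes did not (1.7e-06). Neighbouring genes can share a peak and are not independent.

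Chemoreceptor genes were bound less often, in 10 of 255 cases (3.92%; odds ratio 0.432, 0.204 to 0.815; adjusted p = 0.0312, Fisher's exact test). Those with the highest peaks were sre-23, sre-1 with 350, sri-5 with 315 and srh-269 with 302; the peaks of sre-23 and srh-269 lay at a snoRNA and a tRNA gene. The call did not hold for the 629 IDR peaks of higher signal alone (odds ratio 0.492, adjusted p = 0.224, Fisher's exact test) or with the narrower window (0.477, adjusted p = 0.228, Fisher's exact test).

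The other 13 lists did not pass the threshold in the main comparison, but heat shock, cell cycle and immunity genes each did in 4 of 8 alternatives. Heat shock and chaperone genes came close, with 7 of 32 bound (odds ratio 3.05, 1.11 to 7.30; adjusted p = 0.0529, Fisher's exact test). Their odds ratio was 4.89 without replicate 2 and 2.56 without replicate 1, with overlapping intervals (2.06 to 10.8 and 0.862 to 6.38). The members with the highest peaks were dnj-29 (471), the mitochondrial chaperone gene hsp-60 (386), hsp-1 (334) and dnj-9 (247). Cell cycle and replication genes had 8 of 43 bound (adjusted p = 0.0624, Fisher's exact test), led by lin-35, the retinoblastoma homologue, with a signal of 410 and the centriole gene sas-5 with 346, before knl-3 (290) and bub-1 (288), genes of the kinetochore. Splicing genes had 5 of 22 bound (adjusted p = 0.0711, Fisher's exact test), led by snr-1 (489), snr-4 (266), prp-19 (244) and rnp-2 (212). The odds ratio of the splicing genes fell from 3.20 to 1.33 without replicate 2. Innate immunity and detoxification genes had 4 of 131 bound (odds ratio 0.336, adjusted p = 0.0624, Fisher's exact test): gst-27, clec-126, cyp-31A3 and clec-57. The peaks of gst-27, clec-126 and clec-57 lay at a snoRNA, a tRNA and an snRNA gene. Without peaks at such genes 1 of 131 was bound (odds ratio 0.0948, adjusted p = 0.00572, Fisher's exact test), a comparison chosen after the data were seen.

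Developmental regulators were not bound detectably more often than other genes. Homeobox genes had 2 of 40 promoters bound (5.00%, 95% interval 0.611 to 16.9; odds ratio 0.568), those of ceh-38 (212) and the posterior Hox gene nob-1 (197). Embryonic lineage regulators had 1 of 20 (ref-1, 192) and nuclear hormone receptors 3 of 65 (nhr-255 with 502 at a tRNA gene, nhr-49 with 231 and nhr-228 with 191). Among the remaining lists, muscle structure had 1 of 15 (mlc-1), pan-neuronal 1 of 20 (tbb-1), intestine 0 of 7, which allows up to 42.9% (3 counts of the total), germline 2 of 18 (mes-2 and pgl-1), proteasome 1 of 19 (rpt-1), and collagens and cuticle 4 of 57 (col-185, cutl-23, col-143 and col-63). Each of these 9 lists had an adjusted p of at least 0.697 (Fisher's exact test). In simulations of this test, a 5-fold raised odds was called in 95% of runs for a list of 60 genes and in 47.5% for a list of 20, so the shorter lists leave moderate differences undetected.

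**Figure D4:**
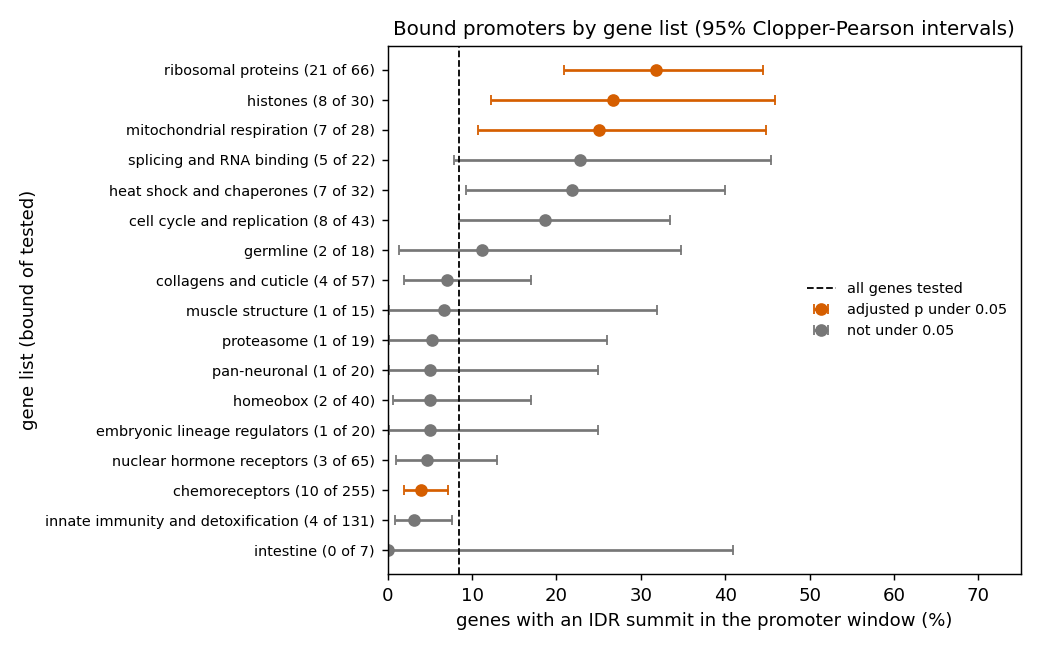
Share of genes with an IDR summit in the promoter window (x axis, percent) for the 17 gene lists, with 95% Clopper-Pearson intervals and the counts bound and tested beside each list. Orange marks an adjusted p under 0.05 and the dashed line the 8.46% of all 7129 genes tested; ribosomal proteins stand highest at 31.8%.

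The sequence TAATTA, which holds the core that many homeodomains bind, was not enriched at CEH-83 summits. It occurred within 50 bp of 29 summits (2.31%) and in 79 flanking windows of the same width (6.28%), a ratio of discordant pairs of 0.351 (27 against 77; exact McNemar p = 9.7e-07, adjusted p = 2.3e-06 over 14 sequences). Summit windows were richer in G and C than background windows (46% ± 9.32 against 38.2% ± 9.01, SD over windows). Against background windows of matched G and C content, where 2.03% held TAATTA, the odds ratio was 1.14 (95% interval 0.724 to 1.75; Fisher's exact p = 0.509). The shorter TAAT was in 41.4% of summit windows and in 41.2% of matched background windows (odds ratio 1.01, 0.890 to 1.15).

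Among the other fixed sequences, GAGAGA and GGGCGG were above both comparisons. GAGAGA was in 13.6% of summit windows, 6.76% of flanks and 9.36% of matched background windows (odds ratio 1.52, 1.26 to 1.84). GGGCGG, the core of Sp1 sites, was in 7.47%, 2.38% and 5.21% (odds ratio 1.47, 1.14 to 1.89). The splice acceptor sequence TTTCAG was below both, in 8.74% of summit windows and 12.8% of matched background windows (odds ratio 0.655, 0.525 to 0.812). Each had an adjusted p of at most 0.0118 against the background (Fisher's exact test) and at most 5.4e-08 against the flanks (exact McNemar test). Without the peaks at tRNA, snoRNA and snRNA genes, GAGAGA and GGGCGG kept odds ratios of 1.62 and 1.72. TTTCAG then moved to 0.768 and lost its call against the background (adjusted p = 0.0814, Fisher's exact test). Over all peaks, TTTTTT was above the matched background (odds ratio 1.24, adjusted p = 0.0118, Fisher's exact test) but below the flanks (ratio 0.573, adjusted p = 1.3e-09, exact McNemar test). TTCTAGAA, a heat shock element, was called above the matched background only (odds ratio 2.87, adjusted p = 0.0480, Fisher's exact test).

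Across all 2080 words of 6 bases, 156 were enriched at summits and 125 depleted at an adjusted p under 0.05. The leading words were AGAGCG (10.3% against 3.16% of matched background windows, odds ratio 3.53), CGAACC (10.1% against 3.06%, 3.56), ACCACT (11.8% against 4.11%, 3.11) and GTTCGA (12.5% against 4.95%, 2.74). GTTCGA and CGAACC overlap the B box, the internal promoter element of tRNA genes. Without the peaks at tRNA, snoRNA and snRNA genes, 50 words were enriched, of which 42 were among the 156. CGCGCA led them (10.1% against 3.98%, odds ratio 2.73, adjusted p = 5.7e-09, Fisher's exact test), followed by GCGCAC (8.96% against 3.34%) and CGCACA (8.64% against 3.55%).

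The X chromosome held more CEH-83 peaks than the background, and no excess was detected once peaks at tRNA genes were left out. There were 254 IDR summits on X (20.2%, against 15.6% of background summits; odds ratio 1.36, 95% interval 1.18 to 1.57; Fisher's exact p = 2.8e-05). X holds 276 of the 612 tRNA genes (45.1%), and 102 of the 236 peaks at tRNA genes were on it (43.2%). Without the peaks at tRNA genes, 152 of 1022 summits were on X (14.9% against 15.5%) and the odds ratio was 0.949 (0.791 to 1.13; Fisher's exact p = 0.598), a comparison chosen after the data were seen. The tRNA genes of X had a summit as often as those of the autosomes (39.5% against 39.6%; odds ratio 0.996, 0.710 to 1.40). Chromosome V held fewer IDR summits than the background (158, 12.6% against 17.7%; odds ratio 0.667, 0.559 to 0.791; adjusted p = 6.9e-06 over 6 chromosomes, Fisher's exact test).

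The native loci of the transgene's genes did not stand apart at the 40 kb scale planned. The strain carries further copies of ceh-83 and of the rescue gene unc-119. The 40 kb window on ceh-83 (II 1715125 to 1755124) held 13 pooled regions against a chromosome median of 12, and 36.2% of the chromosome's windows had as much summed signal. With 20 kb windows the share was 8.35% (summed signal 1424 against a median of 701), and the window held 1 IDR peak, with a signal of 202. The window on unc-119 (III 10885788 to 10925787) held 18 against a median of 15, and 35% of windows had as much. Neither gene had an IDR summit in its promoter window, although each had a summit of the pooled list. The signal is measured against a control whose strain is not given in the sources used here, and extra copies present in both would cancel.

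The replicates shared most peaks, and ranked the strong ones alike more often than the weak ones. Of the 1258 IDR peaks, 929 (73.8%) had a summit within 100 bp among the 1258 highest regions of replicate 1 and 975 (77.5%) among those of replicate 2. Both lists held 703 (55.9%, 95% interval 53.1 to 58.6). The share was 99 of the 100 highest peaks, 90.3% of the 629 of higher signal and 21.5% of the 629 of lower signal (18.3 to 24.9). Of the next 1258 regions of the pooled list, 2 were in both (0.159%), and of 1258 random positions none were, which allows a share of up to 0.238% (3 counts of the total). Weak peaks sit near the edge of these 1258 regions, so their low share is partly set by that limit. The next 1258 pooled regions rank below that edge by construction, so their share near 0 is largely set by it and is no measure of recurrence. Anywhere in both lists of 30000 regions, 605 of the 629 peaks of higher signal (96.2%) and 578 of the 629 of lower signal (91.9%, 89.5 to 93.9) had a summit within 100 bp, against 48.9% of background regions, a comparison chosen after the data were seen. Of the 1258 highest regions of replicate 1, 90.1% were anywhere in the list of replicate 2, and 90.9% the other way. How the number of peaks in this list, deposited as the optimal IDR list, was set is not given in the sources used here. The peaks were drawn from these same libraries, and the pooled signal set which regions these were. The share therefore describes the peaks and tests nothing.

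The signal of the replicates rose together across peaks. Over the 1183 IDR peaks matched in both lists, the Spearman correlation was 0.605 and the Pearson correlation of log2 signal 0.84. Over 13877 matched background regions they were 0.321 and 0.33. These correlations are across regions of the same libraries, which are not independent replicates.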

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

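The enrichment at tRNA, snoRNA, snRNA, microRNA and other non-coding RNA genes kept its direction and side of the threshold under every alternative run. So did the excess in promoters. Under the alternative margins, windows, backgrounds and peak lists, the odds ratio ranged from 35.2 to 79.2 at tRNA genes and 8.41 to 20.7 at snoRNA genes. In promoters it ranged from 1.53 to 2.38. A limit to summits in unique sequence, chosen after the data were seen, gave values outside these ranges, 18.2 at tRNA genes and 24.0 at snoRNA genes. The share of IDR peaks found in both replicates moved with the matching rule: it was 47.7% within 50 bp, 59.8% within 200 bp, 61.4% for any overlap, 60.3% for an overlap of 50% of both intervals, 80.6% with 2516 regions per replicate and 35.3% with 629. Restricting the IDR list to its peaks of higher signal left 629 by construction. The number of lists called, 4 in the main comparison, was 8 against all protein-coding genes and 1 with the window of 500 bp to 100 bp; the cause was not tested. The ratio for TAATTA was 1.14 against the matched background, where the G and C content no longer differed. The number of enriched words, 156, became 63 with windows of 25 bp, 252 with 100 bp and 537 without matching. Among settings chosen after the data were seen, leaving out peaks at tRNA, snoRNA and snRNA genes gave an odds ratio for X of 1.04, 7 lists called and 50 enriched words, and leaving out peaks at tRNA genes gave 0.949 for X. Of 136 odds ratios of gene lists under the alternatives, 4 lost their call, 13 gained one and 0 changed direction with a call. The gains were at heat shock, cell cycle and immunity genes (4 of 8 alternatives each) and at splicing genes (1 of 8). Leaving out a replicate changed the call of heat shock genes (odds ratio 4.89, called without replicate 2) and of immunity genes (0.202, called without replicate 1); without replicate 2 the odds ratio also moved from 3.97 to 5.98 for histones and from 3.20 to 1.33 for splicing genes. Other lists with no call in either setting moved too: without replicate 2, nuclear hormone receptors from 0.521 to 0.267, collagens from 0.816 to 0.341, and, past 1, proteasome from 0.601 to 2.00 and pan-neuronal genes from 0.569 to 1.42 (1.35 without replicate 1). Without replicate 1, germline genes went from 1.35 to 0.674, nuclear hormone receptors to 0.316, and proteasome genes and embryonic lineage regulators to 0. Immunity genes were at 0.509 without replicate 2, against 0.336 in the main comparison. These moves rest on few bound genes, and each setting also replaced the IDR peaks with the highest regions of 1 replicate. Counting error, the change of peak list and the library were not separated. The call at piRNA genes ended with no margin, where no IDR summit was left. A stricter IDR of 0.01 was not run, because the lists hold no scaled IDR. Unknown depth limits how far weak peaks can be told from background.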

Other observations

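The tests in this part on pseudogenes, upstream B boxes, single non-coding genes, each class in unique sequence, and ribosomal protein genes against snoRNA genes or tRNA genes in unique sequence were chosen after the peaks at tRNA and snoRNA genes had been seen. The predictions for the 3 patterns weighed below were written before their tests were run, but the exact B box pattern was written down after GTTCGA had been seen among the enriched words, so its test is not independent of them. Intact tRNA genes and tRNA pseudogenes differed widely in CEH-83 peaks. Of 209 tRNA pseudogenes, 3 had an IDR summit within 200 bp (1.44%, 95% interval 0.297 to 4.14), against 39.5% of tRNA genes (odds ratio 0.0223, Fisher's exact p = 2.4e-33). Most pseudogenes still held a match to the B box (167 of 209), and of these 3 had a summit (1.80%), against 241 of 603 tRNA genes with a match (40%). Among tRNA genes in unique sequence (at least 90% of words around the gene midpoint) 7 of 38 had a summit (18.4%). The others had one in 40.9%. Pseudogenes were not split by uniqueness, so their difference from tRNA genes within unique sequence was not tested.

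Among snoRNA genes, those with a B box within 100 bp upstream of the start stood apart. An IDR summit was found at 28 of 44 of them (63.6%) and at 36 of 302 without the box (11.9%; odds ratio 12.9, 95% interval 6.03 to 28.0; Fisher's exact p = 5.3e-13). A peak with a signal of 748 at I 13463775 to 13464218 lay at rpr-1, the gene of the RNA component of RNase P, in an intron of ints-8. The peak at mir-51 (IV 11026104 to 11026346, signal 1471) held a B box match, GTGTCGAAC, and that at mir-52 (IV 14033877 to 14034215, signal 1319) held none. Of the 50 highest peaks away from tRNA, snoRNA and snRNA genes, 5 held a match, against 39 of the other 887 (4.4%; Fisher's exact p = 0.0791).

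For the peaks at tRNA and snoRNA genes, the prediction for reads shared between near-identical gene copies was not met. Among summits in at least 90% unique sequence the joint odds ratio was still 22.8 (95% interval 17.3 to 30.1, 41.1 without that limit). Of the 100 summits behind it, 67 were at snoRNA genes, nearly all of whose summits lay in unique sequence. At snoRNA genes the odds ratio was 24.0 (18.2 without the limit), which argues against shared reads as the whole cause there. At tRNA genes alone it fell from 50.5 to 18.2 (11.3 to 29.0), resting on 33 of 236 summits. Only 7 tRNA genes with a summit were themselves in unique sequence by the gene midpoint. Shared reads therefore stay open for the tRNA signal. High transcription stays open. Ribosomal protein genes, taken as strongly transcribed, had an IDR summit within 200 bp of their start less often than tRNA genes (odds ratio 0.0764), but that bound was poorly chosen: their summits lay a median of -317 bp from the start, and most tRNA genes lie in repeated sequence. With the promoter window, 21 of 84 ribosomal protein genes had a summit. That was fewer than among all tRNA genes (242 of 612, odds ratio 0.510, 0.288 to 0.874, Fisher's exact p = 0.0114). It was not detectably different from 7 of 38 tRNA genes in unique sequence (odds ratio 1.48, 0.529 to 4.55) or 64 of 346 snoRNA genes (1.47, 0.791 to 2.65). These windows are unlike, as the promoter window is longer than a tRNA or snoRNA gene with 200 bp to either side. Within 200 bp of the start, 4 of 84 ribosomal protein genes had a summit (4.76%). Neither window decides the question. The odds were raised at ribosomal protein (5.20), histone (3.97) and respiration genes (3.64) and lowered at chemoreceptors (0.432). All but the ribosomal protein call ended with the narrower promoter window. The odds of proteasome genes were not detectably raised (0.601, with 1 of 19 bound). These values concern protein-coding promoters of the same peaks, so they are no test of the peaks at tRNA and snoRNA genes. Transcription was not measured, so how strongly each list is transcribed is not known here. The prediction of a B box at snoRNA summits was met. One was held by 27 of 68 summits, against 44 of 954 other summits away from tRNA genes (odds ratio 13.6, 7.32 to 24.9, Fisher's exact p = 2.8e-16). Their flanks held one in 2 of 68 cases (exact McNemar p = 4.2e-07). The pattern was written down after enriched words had been seen, and GTTCGA led the words at these snoRNA summits too (27.9% against 3.97% of background windows). These values therefore describe the summits and are not independent support. A hypothesis open to test is that tagged CEH-83, or chromatin that this immunoprecipitation recovers regardless of the tag, may be held at active genes of RNA polymerase III, since most B box matches in pseudogenes had no summit. Neither the polymerase nor the activity of these genes and pseudogenes was measured, and the 2 were not compared within unique sequence. No biological difference between groups was tested, as there is 1 group, and without a library of untagged animals these readings stay open.

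For the excess of peaks on the X chromosome, the density of tRNA genes on X is a candidate explanation. The odds ratio was 1.36 (1.18 to 1.57) with all peaks and 0.949 (0.791 to 1.13) without those at tRNA genes; the call ended because the share on X fell from 20.2% to 14.9%, below the background's 15.5%. No other explanation was tested.

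Extra copies of the transgene loci could have raised the regions around ceh-83. No excess was seen at the scale planned, where 36.2% of the 40 kb windows of its chromosome held as much summed signal (8.35% with 20 kb windows and 49.5% with 80 kb). The explanation stays open, because the signal is measured against a control whose strain is not given in the sources used here, and copies present in both would cancel.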
